A study of Arabidopsis thaliana with 3 samples.

How the data were processed

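RNA was measured in 3 libraries of wild-type Arabidopsis thaliana seedlings of the accession Col-0, the common laboratory strain, which the labels number 4, 5 and 6. Per the labels' protocols, total RNA was extracted with a column kit, ribosomal RNA was removed, and directional libraries were sequenced on an Illumina HiSeq instrument. The protocols name no selection of polyadenylated RNA. The deposited files hold 1 value per gene and library for 27416 genes under AGI locus identifiers. The submitters' processing notes name TopHat2 2.0.9, Cufflinks 2.1.1 and the genome build TAIR10, without saying which of them made the values. The column headers give no unit. The values were taken as FPKM made by the authors (fragments relative to gene model length and to the total of assigned fragments), because Cufflinks is named. The values are whole reads divided by a length and a library total, which is unusual for Cufflinks, whose estimates need not be whole. RPKM from whole read counts is thus equally possible, and the sources used here do not tell the 2 apart. Every value printed as FPKM carries this doubt about its name. The strand setting and the treatment of reads with several matches are not given in the sources used here, so genes with near-identical copies, overlapping genes and antisense partners are less certain than others.

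The deposited FPKM values could be turned back into whole reads. Library totals were found from the values of genes at their annotated length, and with those totals all 20669 genes above 0 in each of the 3 libraries came out as whole reads, within a tolerance of 0.0001 reads plus 1e-09 of the reads. The reads of a gene are the smallest whole numbers that fit its values. They were used where the length they imply was close to the annotated one, as in 16530 genes, and are only a minimum elsewhere. The totals were 19921241 reads in replicate 4, 19905762 in replicate 5 and 19892527 in replicate 6, a range of 0.144%. The recovery was tested on simulated data, where 100% of 2269 genes with a clear length (of 2439 with simulated reads) gave back their exact reads. Simulated lengths equalled the annotated ones or lay below them within the length rule, so that rule removed nearly any wrong fit. The 100% thus says little about wrong fits in genes longer than annotated, which were not simulated. In a gene of 1000 bp, 1 read was worth 0.0502 FPKM, and a count of 0 allows up to 0.151 FPKM (3 counts). Such limits cover counting error only. The recovered reads were used for depth, for limits of zeros and for the spread between libraries. No count model was fitted, since there is 1 group.

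Levels of genes and contrasts are means ± SD over 3 libraries (n = 3) of the deposited FPKM or of the difference in each library. Differences and log2 ratios are on the log2(FPKM + 1) scale. This scale understates differences that involve low genes, and the SDs of those differences. A gene counted as detected at 1 FPKM or more in every library. The background was 27197 nuclear protein-coding genes. It leaves out 88 chloroplast rows, 122 mitochondrial rows and 9 nuclear rows that the annotation puts in another class, and it keeps nuclear identifiers that the annotation lacks. For gene names, classes and coordinates, 26719 of the identifiers (97.5%) matched the gene table of the assembly TAIR10.1. The files hold no coordinates, and every coordinate given is 1-based on TAIR10.1. Among 397 entries of the gene lists, 361 symbols stand in that table and 36 are literature names, tied to their locus identifiers by hand.

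The choices in this paragraph, apart from the further examples in its last sentence, were made before the data were examined. The lists were 26, with 396 different genes, all found in the files. The level of a list is the median over its members minus the median of the background, both on log2 values averaged over the 3 libraries. The same difference within each library is given as a range, without an SD. A contrast of 2 lists is the mean of its values within each library and need not equal the difference of the 2 list levels. The level of each list was placed among 10000 random lists of the same size and called above or below when it fell outside the central 95%. The spread of a list is the median SD of log2(FPKM + 1) over members at a mean of 1 FPKM or more, placed among 10000 random lists matched on mean level in 20 bins, and lists with fewer than 3 such members were left out. These percentiles describe the libraries at hand and are not p-values, since genes are not replicates. There were 17 fixed contrasts between genes or lists. With 3 libraries an exact two-sided sign-flip test cannot give a p below 0.25, so none was run and the number of libraries with each sign is given. Pericentromeres were windows of 3 Mb on either side of fixed centromere midpoints. The genes named are the 2 highest and the lowest member of each list, the partners of each contrast, the 10 genes with the highest level and the 10 with the largest SD at a mean of 10 FPKM or more. Further members are named as examples and were chosen after their values were seen.

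The list procedures were tested on simulated data of 27197 genes. Of random lists of 20 genes raised 8-fold on the FPKM + 1 scale, 93.3% were called above, and 0% of unchanged lists were called. Smaller shifts were not simulated. For lists whose spread was raised 4-fold, from an SD of 0.1 to 0.4 in natural logs, 100% were called, against 1.43% of unchanged lists. All unchanged genes were given the same relative noise there, whereas real spread fell with depth. The simulation therefore does not test whether the matching on level removes that fall. Sequence sharing was measured as the share of a gene's 50-base words that occur in another gene. Alternatives were another pseudocount, 2 other scalings, other filters, other window sizes, a mean in place of the median, and leaving out each library in turn. A level against genes at 1 FPKM or more leaves out genes with a lower mean from the list as well as from the background. The spread by the variance-to-mean ratio of recovered reads was an alternative chosen after seeing the data. Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.

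The labels do not say whether the libraries came from separate plants. SDs and spreads therefore measure only the differences between these libraries, which may be technical. A comparison between conditions was not possible with 1 group.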

Results

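The transcriptome of whole Arabidopsis seedlings was measured at 3 weeks of age, in a series whose title concerns DNA N6-adenine methylation. The plants were wild-type Col-0, kept on agar plates with MS medium, with 16 h of light and 8 h of dark at 23 ± 2 °C. There was 1 group of 3 libraries, with recovered library totals of 19921241, 19905762 and 19892527 reads in replicates 4, 5 and 6. With no second group, the data give the levels of genes within these plants and the differences between the libraries.

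Genes of photosynthesis led the transcriptome. The highest nuclear gene was LHCB1.3 (also CAB1, AT1G29930, chromosome 1, 10477885 to 10479114, TAIR10.1), a chlorophyll-binding antenna protein of photosystem II, at 13523 ± 137 FPKM (SD, n = 3). It was followed by RBCS1A (AT1G67090, chromosome 1, 25048158 to 25049667), a small subunit of the CO2-fixing enzyme Rubisco, at 10938 ± 89.8 FPKM, and by the antenna gene LHCB1.5 (LHB1B2) at 8426 ± 148 FPKM. The other genes among the top 10 were the growth regulator TCTP (6109 ± 6.47 FPKM), the clock-controlled RNA-binding protein GRP7 (5529 ± 43.2 FPKM), the photosystem II subunit PSBR (5482 ± 64.6 FPKM), RBCS3B (5402 ± 203 FPKM), RBCS2B (5135 ± 76.7 FPKM), the thiamine synthesis enzyme THI1 (4066 ± 65.7 FPKM) and LHCB1.4 (LHB1B1, 3614 ± 81.7 FPKM). LHCB1.3, LHCB1.5, RBCS3B and RBCS2B share 17.0%, 17.3%, 18.3% and 21.4% of their 50-base words with other genes, so the division of reads within these families is uncertain.

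The top 10 genes held 9.32 ± 0.053% of summed FPKM, the top 100 held 26.4 ± 0.098% and the top 1000 held 56.6 ± 0.094% (n = 3). In all 3 libraries 17239 of 27416 genes (62.9%) were detected, and 5008 (18.3%) were at 0 throughout. Per library, 17572, 17620 and 17616 genes were detected. The median nuclear gene had 4.71 FPKM, the gene at the 90th percentile 46.6 FPKM and the gene at the 99th percentile 341 FPKM. A mean of 1000 FPKM or more was reached by 74 genes.

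The 3 libraries were close to one another. Across nuclear protein-coding genes, Pearson's r of log2(FPKM + 1) was 0.998 and Spearman's rho 0.993 in each pair. These values are across genes, which are not independent replicates. None of 10042 genes with a mean of 10 FPKM or more differed by more than 2-fold in FPKM + 1 between the highest and lowest library. Without a filter on low values 32 of 27197 genes did, and 14 of 17483 did at a mean of 1 FPKM or more. Low genes seldom reach 2-fold on this scale. FT, for example, ran from 1.06 to 2.17 FPKM and is not counted. RTFL14, of a family of small peptides that affect leaf shape, had the largest SD among the 10042 genes at 10 FPKM or more, 0.43 on the log2 scale, at 11.4 ± 3.59 FPKM. The others among the 10 largest were AT3G13240, AT5G23411, AT3G26539, AT4G25707, AT2G46567, AT4G30660, AT3G09162, AT1G73120 and AT1G45248, with SDs from 0.32 down to 0.27. For 5 of these 10 genes the length behind the values was clear, and they had 71 to 483 reads over the 3 libraries together.

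The libraries differed by little more than counting noise in most genes. The variance of recovered reads was 1.35 times the mean in genes of 100 to 300 reads and 1.52 times the mean in genes of 3000 to 10000 reads. In the 35 genes with 100000 reads or more it was 12.0 times the mean on average, with a scaled median of 3.96. The average was drawn up by a few genes, such as RBCS3B (148), LHCB1.5 (54.2) and THI1 (32.4). Over all 35 genes the median coefficient of variation was 0.789%. Ratios above 1 mean that the libraries differed by more than Poisson counting, and they were kept as 3 libraries.

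The first comparison set gene groups against all nuclear protein-coding genes. Groups of photosynthesis and protein synthesis stood far above that background. The 16 Calvin cycle enzymes, which fix CO2, were all detected, and their median lay 7.86 above the background on the log2 scale (7.85 to 7.86 in single libraries). For each list the lowest and highest value from a single library follow in parentheses. The list value itself is a median of genes averaged over the 3 libraries, so it can lie outside that range. RBCS1A and RBCS3B were highest, and the plastid triosephosphate isomerase PDTPI was lowest at 368 ± 7.56 FPKM. The 20 light-harvesting proteins were also all detected, with a median 7.45 (7.43 to 7.46) above the background. Their levels ran from LHCB1.3 and LHCB1.5 down to LHCB4.3 at 6.08 ± 0.735 FPKM. The 22 ribosomal proteins lay 5.19 (5.16 to 5.19) above the background, led by RPL10A (464 ± 0.641 FPKM) and RPL3A (436 ± 6.23 FPKM), with RPL10B at 12.7 ± 0.524 FPKM. The 16 genes in common use as qPCR references lay 3.92 (3.88 to 3.96) above it, from UBQ10 (1046 ± 18.6 FPKM) and EF1A (729 ± 6.63 FPKM) down to UPL7 (5.79 ± 0.347 FPKM). In the same seedlings 11 of 12 genes of nitrate assimilation were detected, 3.83 (3.8 to 3.86) above the background. The plastid glutamine synthetase GLN2 had 1219 ± 4.06 FPKM and the nitrate reductase NIA2 had 840 ± 12.2 FPKM, whereas the high-affinity nitrate transporter NRT2.1 had 0.0088 ± 0.015 FPKM. Each of these 5 lists ranked above all 10000 random lists.

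**Figure D1:**
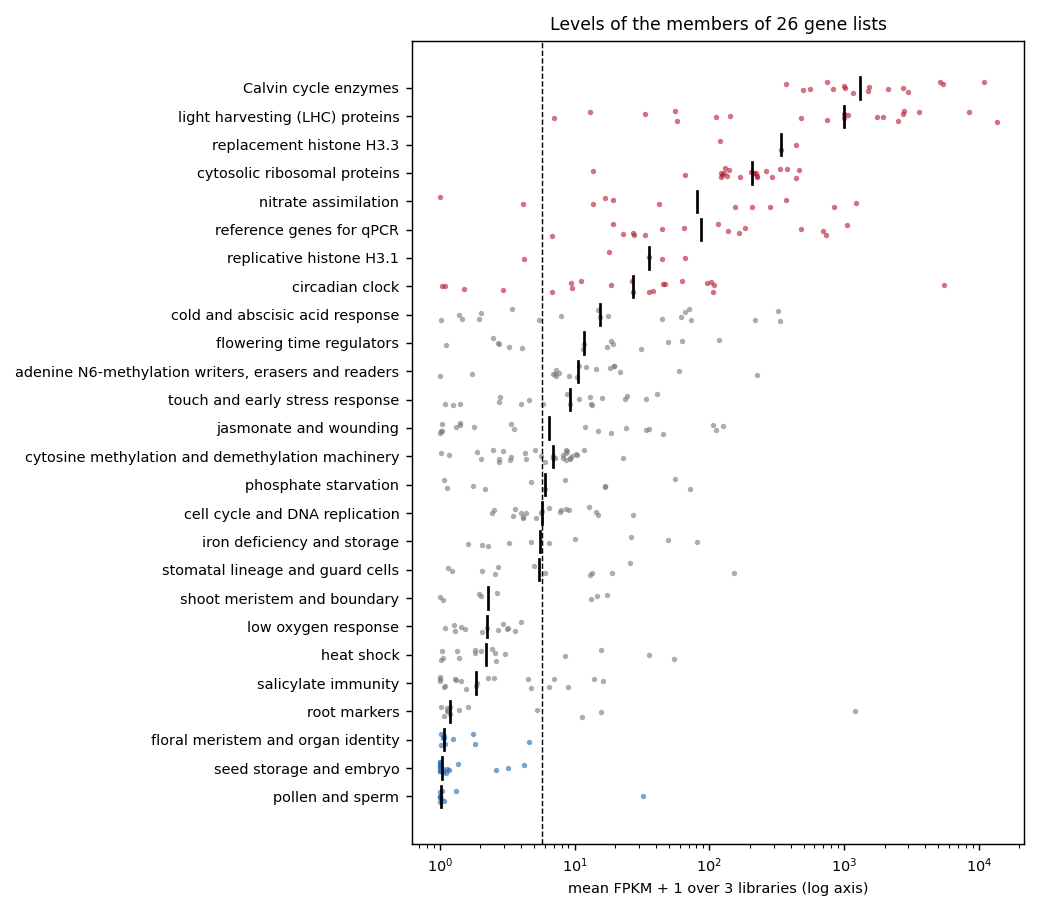
Mean FPKM + 1 over 3 libraries (horizontal, log axis) of every member of the 26 gene lists (rows, sorted by median FPKM). Points are genes, black bars are list medians on the log2 scale, the dashed line is the median of nuclear protein-coding genes, and red, blue and grey mark lists called above, called below and within the range of random lists. The 8 lists above include Calvin cycle enzymes and light-harvesting proteins, and the 3 lists below are floral identity, seed storage and pollen genes.

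Within the photosynthesis families the highest member held a large share. It was 50.9 ± 0.21% of the LHCB1 sum and 45.2 ± 0.41% of the sum of 4 RBCS genes, though the division of reads within families is uncertain. RBCS1A alone was at 10938 ± 89.8 FPKM against 13278 ± 192 FPKM for the sum of RBCS1B, RBCS2B and RBCS3B, a log2 ratio of -0.28 ± 0.024 that was below 0 in 3 of 3 libraries. The 5 LHCB1 genes summed to 26592 ± 379 FPKM, and the 3 LHCB2 genes to 123 ± 2.47 FPKM. The median of the light-harvesting list was lower than that of the Calvin cycle list by a log2 difference of -0.41 ± 0.013, in 3 of 3 libraries.

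The machinery of methylation was next, since the series concerns a DNA mark. Most of its genes were expressed at moderate levels. The list for N6-methyladenine includes genes that act on mRNA, such as MTA, MTB and ALKBH10B, so its level does not measure a DNA mark. Of 18 genes for writers, erasers and readers of N6-methyladenine, 16 were detected, and the list median lay 0.90 above the background (0.86 to 0.92, 85.5th percentile of random lists, within their range). Against genes at 1 FPKM or more the sign turned, to -0.25 (30.4th percentile). The cytoplasmic reader ECT2 (AT3G13460, chromosome 3, 4384563 to 4388592, TAIR10.1) was highest at 226 ± 1.87 FPKM, followed by ECT3 at 58.5 ± 1.38 FPKM. The mRNA methyltransferase subunits MTA (AT4G10760, chromosome 4, 6619817 to 6623381) and MTB (AT4G09980, chromosome 4, 6247735 to 6252314) had 9.46 ± 0.710 and 9.82 ± 0.329 FPKM. METTL4-like (AT1G19340, chromosome 1, 6684467 to 6687116), a homolog of an adenine methyltransferase of animals, had 6.28 ± 0.73 FPKM, and ALKBH1A, of a family of oxygenases that includes demethylases, had 6.28 ± 0.119 FPKM. ALKBH9A was at 0 in every library, which allows up to 0.0823 FPKM.

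Of 31 genes for cytosine methylation and demethylation, 27 were detected, and their median lay 0.27 above the background (0.15 to 0.26, 64.8th percentile). The sign of this small difference depended on the summary: the mean over members lay -0.17 from the background, and against genes at 1 FPKM or more the median lay -0.96 from it, below all but 0.55% of random lists. SUVH9, a protein that recruits the RNA-directed pathway, was highest at 21.7 ± 0.623 FPKM, followed by RDM1 at 10.8 ± 0.397 FPKM, and the de novo methyltransferase DRM1 was lowest at 0.027 ± 0.027 FPKM. The maintenance methyltransferase MET1 (AT5G49160, chromosome 5, 19932114 to 19938470) had 6.12 ± 0.173 FPKM, and the chromomethylases CMT3 and CMT2 had 5.93 ± 0.194 and 7.22 ± 0.366 FPKM.

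Paralogs and partners of this machinery differed in some pairs. DRM2 (7.75 ± 0.415 FPKM) exceeded DRM1 by 3.09 ± 0.10 on the log2 scale, ECT2 exceeded ECT3 by 1.93 ± 0.045, and the mRNA demethylase ALKBH10B (18.6 ± 0.594 FPKM) exceeded ALKBH9B (6.69 ± 0.221 FPKM) by 1.35 ± 0.063, each in 3 of 3 libraries. The DNA glycosylase ROS1 (4.11 ± 0.335 FPKM) was below DME (8.52 ± 0.102 FPKM), with a log2 ratio of -0.90 ± 0.098, and CMT3 was below CMT2, with -0.25 ± 0.059, in 3 of 3 libraries. MTA and MTB differed by -0.05 ± 0.14 and MET1 and CMT3 by 0.04 ± 0.075, less than the spread between libraries, with both signs among the libraries. The median of the adenine list exceeded that of the cytosine list by 0.68 ± 0.079 in 3 of 3 libraries. An exact two-sided sign-flip test over 3 libraries cannot give a p below 0.25, and no p-value is given.

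**Figure D2:**
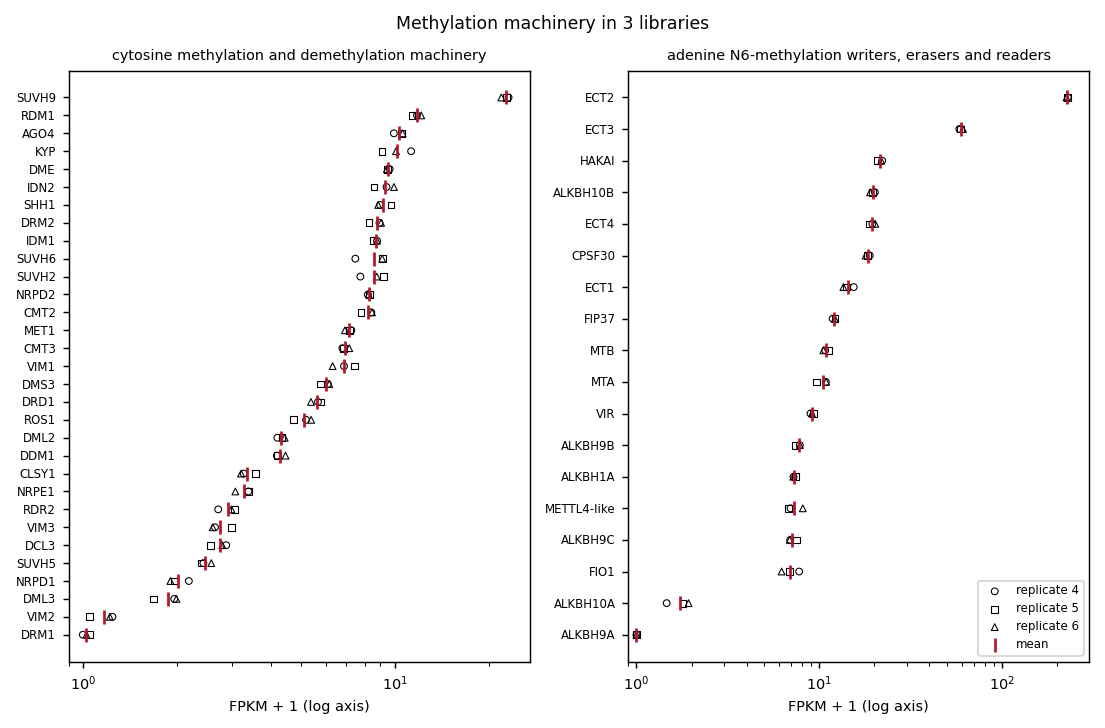
FPKM + 1 (horizontal, log axis) of the genes for cytosine methylation (left) and N6-methyladenine (right), sorted by mean. Circles, squares and triangles are replicates 4, 5 and 6, and red ticks are means. ECT2 stands highest on the right at 226 FPKM, and ALKBH9A is at 0 in each library.

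Most listed genes of histone H3 were above the median nuclear gene, and the median of cell division genes lay near it. The 3 genes of the replacement histone H3.3, which is built in outside replication, lay 5.89 (5.85 to 5.91) above the background. HTR5 had 439 ± 6.75 FPKM, HTR4 337 ± 7.85 FPKM and HTR8 119 ± 4.61 FPKM. The 5 genes of the replicative histone H3.1 lay 2.65 above it (2.59 to 2.75, 97.9th percentile), from HTR1 (65.2 ± 0.955 FPKM) and HTR2 (43.3 ± 2.80 FPKM) to HTR3 (3.24 ± 0.094 FPKM, with 35.6% shared words). The H3.1 call did not hold against genes at 1 FPKM or more (93.5th percentile) or with the mean over members (97.1). The sum of H3.1 genes, 164 ± 3.19 FPKM, was below that of H3.3 genes, 895 ± 11.3 FPKM, by a log2 ratio of -2.44 ± 0.043, in 3 of 3 libraries. Of 20 genes of cell cycle and DNA replication 19 were detected, and their median lay 0.0026 (-0.027 to 0.034) from the background (51.4th percentile). The ribonucleotide reductase genes TSO2 (26.3 ± 1.13 FPKM) and RNR2A (13.9 ± 0.118 FPKM) led, and the mitotic cyclin CYCB1;1 was lowest at 1.44 ± 0.299 FPKM. Against genes at 1 FPKM or more this list was below, at -1.26 (0.26th percentile).

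Genes that time flowering were expressed, and genes that build flowers were mostly near 0. Of 15 flowering time regulators 14 were detected, with a median 1.05 above the background (1.04 to 1.06, 88.2th percentile), or 0.069 above it against genes at 1 FPKM or more (55.6th percentile). The repressors SVP (116 ± 1.17 FPKM) and TEM1 (62.0 ± 0.638 FPKM) were highest, and the FT homolog TSF was lowest at 0.105 ± 0.036 FPKM. The floral repressor FLC (AT5G10140, chromosome 5, 3173382 to 3179448, TAIR10.1) had 29.9 ± 2.14 FPKM, and the flowering signal FT (AT1G65480, chromosome 1, 24331373 to 24333999) had 1.76 ± 0.614 FPKM. FT was thus below FLC, with a log2 ratio of -3.51 ± 0.41, and above TSF, with 1.3 ± 0.37, in 3 of 3 libraries. Of 10 genes of floral meristem and organ identity, only SEP3 (3.58 ± 0.467 FPKM) was detected. SHP1 followed at 0.821 ± 0.452 FPKM and SEP2 was lowest at 0.012 ± 0.020 FPKM. This list lay below the background by a log2 difference of -2.40 (-2.40 to -2.35, 2.13th percentile), and of -4.80 with a pseudocount of 0.1. Without replicate 5 its percentile was 2.78, inside the range of random lists. The flowering time list exceeded the floral identity list by 3.42 ± 0.018 in 3 of 3 libraries.

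Clock genes stood at contrasting levels. As a group the 21 genes of the circadian clock, the internal day timer, lay 2.25 above the background (2.19 to 2.28, 99.99th percentile), and 18 were detected. Against genes at 1 FPKM or more the difference was 1.44 (99.8th percentile). GRP7, a clock output, was highest, and TOC1 (AT5G61380, chromosome 5, 24674963 to 24678550, TAIR10.1), an evening-phased repressor, was second at 107 ± 0.481 FPKM. The evening complex genes ELF4 and LUX had 104 ± 3.89 and 102 ± 1.35 FPKM. RVE4, a relative of CCA1 and LHY, had 95.4 ± 0.858 FPKM. The morning-phased genes CCA1 and LHY had 0.516 ± 0.056 and 0.087 ± 0.071 FPKM, and PRR9 was lowest at 0.037 ± 0.016 FPKM, with 29.9% shared words. CCA1 was below TOC1, with a log2 ratio of -6.15 ± 0.050, and LHY was below the evening gene GI (17.76 ± 0.876 FPKM), with -4.11 ± 0.029, in 3 of 3 libraries. The 1 FPKM added before the log2 narrows both ratios and their SDs. LHY itself ran from 0.0375 to 0.169 FPKM over the libraries.

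**Figure D3:**
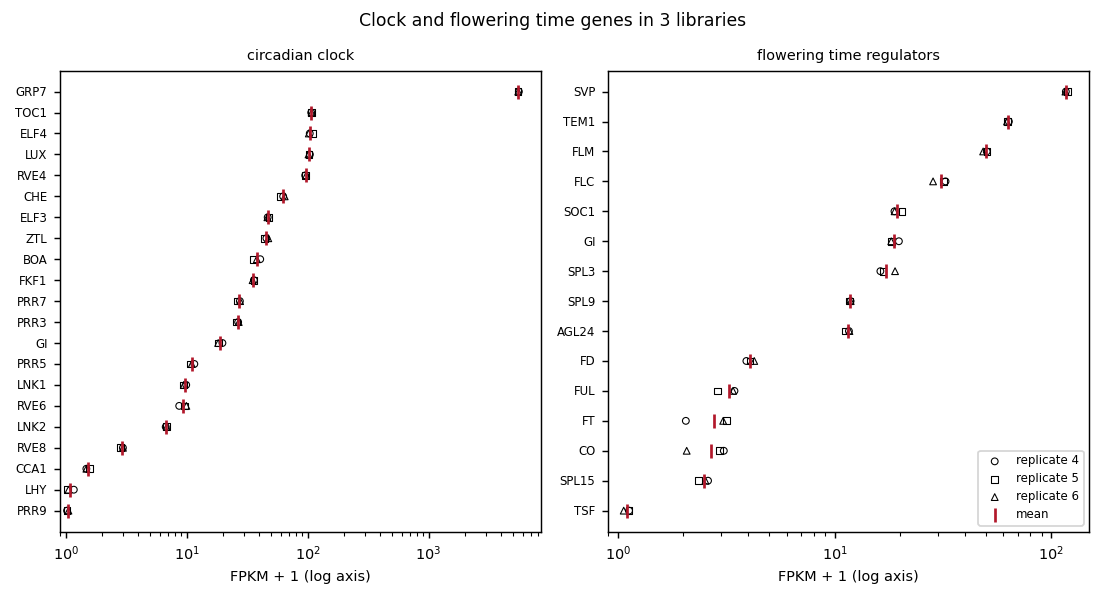
FPKM + 1 (horizontal, log axis) of circadian clock genes (left) and flowering time regulators (right), sorted by mean. Circles, squares and triangles are replicates 4, 5 and 6, and red ticks are means. CCA1, LHY and PRR9 lie at the lower end on the left, below 1 FPKM, and SVP leads on the right at 116 FPKM.

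Groups of stress response lay within the range of random lists. The list of cold and abscisic acid response came closest to the upper bound, 1.45 above the background (1.42 to 1.47, 97.2th percentile), with COR47 at 334 ± 6.38 FPKM, KIN2 at 320 ± 12.9 FPKM and GOLS3 at 0.013 ± 0.022 FPKM. It was called above by the mean over members (99.6th percentile) and against genes at 1 FPKM or more (99.8). The touch and early stress list lay 0.70 (0.58 to 0.69) above the background, 0.33 above it with the mean over members, but -0.21 from it against genes at 1 FPKM or more (34.1 percentile). Its levels ran from ERF104 (39.6 ± 0.426 FPKM) and MPK3 (33.1 ± 0.612 FPKM) down to RRTF1 (0.085 ± 0.021 FPKM). Jasmonate and wounding genes lay 0.19 (0.14 to 0.22) above it, 0.36 with the mean over members and 1.07 against genes at 1 FPKM or more (96.8th percentile). The synthesis enzymes AOC2 and LOX2 had 125 ± 2.53 and 111 ± 0.974 FPKM, and TAT3 was at 0, which allows up to 0.0629 FPKM.

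Other stress lists lay lower. Heat shock genes had a median difference of -1.36 (-1.50 to -1.26, 12.9th percentile), or -0.86 with the mean over members, led by HSP70-4 (53.9 ± 0.682 FPKM) and MBF1C (34.4 ± 1.2 FPKM), with HSP21 at 0.018 ± 0.031 FPKM. Low oxygen genes had -1.34 (-1.44 to -1.14, 17.0th percentile), with HRA1 at 2.99 ± 0.226 FPKM, HRE1 at 2.62 ± 0.553 FPKM and SUS4 at 0.085 ± 0.028 FPKM. Both were below against genes at 1 FPKM or more, at -2.18 and -2.16. Of 20 genes of salicylate immunity 8 were detected, with a difference of -1.62 (-1.65 to -1.59, 7.15th percentile), or -1.2 by the mean over members (0.62th). The salicylate receptor NPR1 had 15.2 ± 0.337 FPKM and WRKY70 12.9 ± 0.963 FPKM. The defence markers PR1 and PR2 were at 0 in every library, which allows up to 0.167 and 0.102 FPKM. The wound-responsive storage protein VSP2 had 13.9 ± 0.970 FPKM, above PR1 in 3 of 3 libraries.

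Nutrient lists other than nitrate lay within the range of random lists. Phosphate starvation genes lay 0.079 (0.0028 to 0.12) from the background, or -0.19 against genes at 1 FPKM or more. The sulfolipid enzymes SQD1 and SQD2 had 71.1 ± 0.399 and 54.5 ± 2.06 FPKM, and SPX3, a sensor gene that rises in phosphate starvation, had 0.073 ± 0.032 FPKM. Genes of iron deficiency and storage had a median difference of -0.050 (-0.12 to 0.017), which became -1.09 against genes at 1 FPKM or more (5.67th percentile) and 0.38 with the mean over members. In that list the ferritins FER1 (79.8 ± 2.96 FPKM) and FER3 (48.3 ± 1.55 FPKM) were highest and the iron reductase FRO2 was lowest at 0.619 ± 0.084 FPKM.

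Markers of organs and cell types were read as RNA levels, which do not measure how much of a tissue the seedlings held. Seed storage and embryo genes were below the background by a log2 difference of -2.45 (-2.52 to -2.43, 0.52th percentile), and of -5.17 with a pseudocount of 0.1. Of 17 genes 3 were detected and 8 were at 0 in every library. EM6 had 3.18 ± 0.170 FPKM and OLEO2 2.21 ± 0.674 FPKM, and the storage protein gene CRU2 was at 0, which allows up to 0.0924 FPKM. Pollen and sperm genes were below as well, at -2.49 (-2.51 to -2.49, 0.58th percentile), and at -5.44 with a pseudocount of 0.1. The tubulin TUA1 was detected at 30.9 ± 1.1 FPKM, GEX2 had 0.307 ± 0.025 FPKM, and 5 genes were at 0. Among its members at 1 FPKM or more the seed storage list reached the 2.62th percentile. That filter takes out the low members that made the call, so it is no separate test of it.

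Root markers had a median difference of -2.26 (-2.25 to -2.13, 4.03th percentile, within range), and 4 of 13 were detected. The difference was -0.84 with the mean over members, -0.033 against genes at 1 FPKM or more (49.1th percentile) and -4.08 with a pseudocount of 0.1. The value of -0.033 rests on the 4 root markers with such a mean. PYK10 (AT3G09260), a beta-glucosidase of roots, had 1196 ± 3.50 FPKM and the endodermis regulator SCR 14.6 ± 0.066 FPKM, whereas the root hair expansin EXP7 had 0.016 ± 0.028 FPKM. Genes of stomata lay -0.058 (-0.093 to -0.0052) from the background, -0.63 against genes at 1 FPKM or more and 0.16 with the mean over members, with GC1 at 150 ± 10.2 FPKM, SCRM at 24.8 ± 0.416 FPKM and MUTE at 0.142 ± 0.093 FPKM. Genes of the shoot meristem had -1.32 (-1.30 to -1.27, 19.8th percentile), with -0.68 for the mean over members and -0.055 against genes at 1 FPKM or more (49.1th percentile). The value of -0.055 rests on 5 of the 8 members. KNAT1 and CLV1 had 16.4 ± 0.252 and 13.8 ± 0.127 FPKM, and the stem cell regulator WUS was at 0, which allows up to 0.121 FPKM.

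The next comparison asked which gene groups differed most and least between libraries. Calvin cycle enzymes had a median SD of 0.013 on the log2 scale (1.90th percentile of matched lists) and light-harvesting proteins of 0.017 (1.59th percentile), both called below. Seed storage genes, with 3 members tested, were called above with 0.28 (98.8th percentile). The other 21 of 24 testable lists were within range. None of these calls was stable. Both photosynthesis calls ended without any one of the libraries. The seed storage call ended without replicate 4 (0.17, 83.7th percentile) and without replicate 6 (0.079, 42.7th percentile). By the variance-to-mean ratio of recovered reads, an alternative chosen after seeing the data, the Calvin cycle list was called above (4.19, 99.9th percentile). The SD fell and this ratio rose with reads per gene, and matching on level is coarse for the highest genes. Neither call for the Calvin cycle list can thus be told from depth. Across 72 values for lists in single libraries, 3 lay outside the central 95%, where chance gives 3.6. They were touch and early stress genes in replicate 4 (98.3th percentile) and in replicate 6 (2.45th), and seed storage genes in replicate 6 (0.2th).

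Genes of the organelle genomes made up a small share. Chloroplast genes held 0.0686 ± 0.0037% of summed FPKM and mitochondrial genes 0.0475 ± 0.0012% (n = 3). Of 88 chloroplast genes 57 were detected, with a median of 2.3 FPKM, and ATCG01020 was highest at 78.0 ± 3.38 FPKM. Of 122 mitochondrial genes 34 were detected, and ATMG01080 was highest at 63.8 ± 3.53 FPKM. Nuclear genes held 99.9%.

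Genes near centromeres were less often expressed than genes on chromosome arms. The median of 2963 genes within 3 Mb of a centromere was lower than that of 23747 genes on arms, by a log2 difference of -2.12 ± 0.0091 (n = 3, lower in each library). Among pericentromeric genes 45.6% were detected, against 66.4% on arms. Among detected genes the medians were 12.9 and 13.1 FPKM. The difference was below 0 on each chromosome, with -1.83 on chromosome 1, -2.32 on 2, -2.65 on 3, -1.3 on 4 and -2.20 on 5. It depended on the window, with -1.12 for 5 Mb and -2.46 for 2 Mb, and on the pseudocount, with -3.21 for 0.1.

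**Figure D4:**
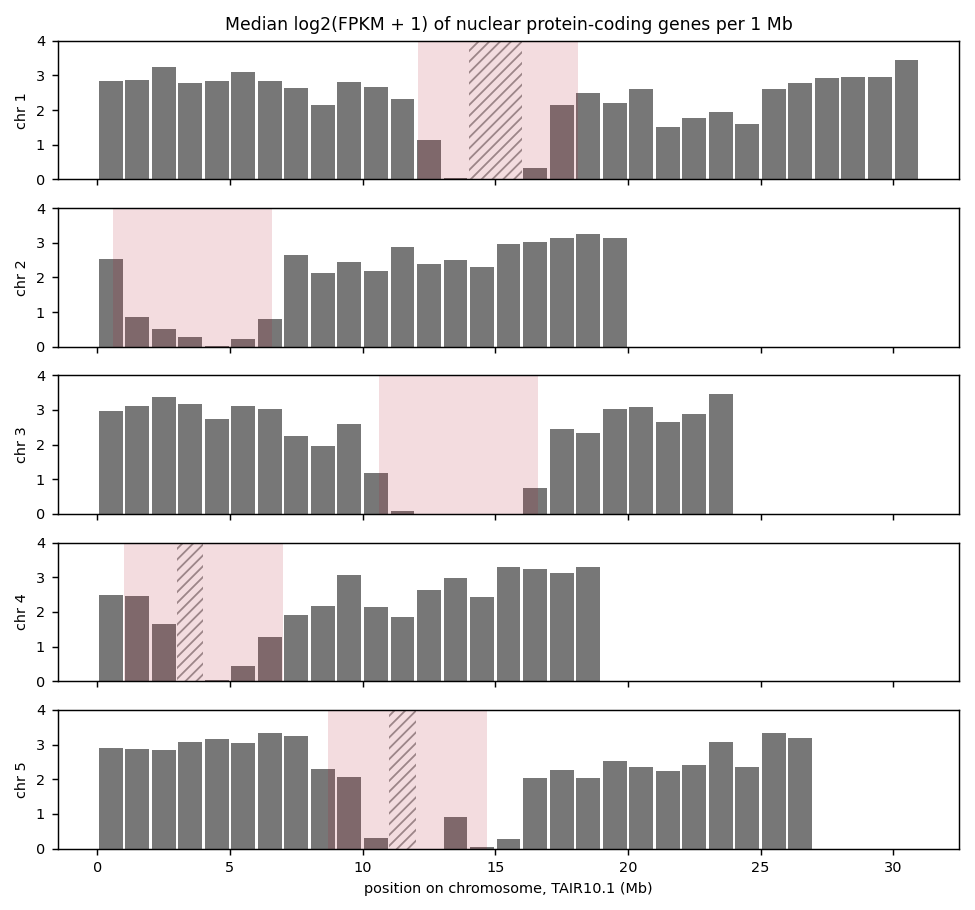
Median log2(FPKM + 1) of nuclear protein-coding genes (vertical) in windows of 1 Mb along chromosomes 1 to 5 (horizontal, Mb on TAIR10.1), for windows with at least 20 genes. Hatched windows hold fewer genes and are not drawn, a window with no bar and no hatching has a median of 0 or close to it, bars are medians of the mean over 3 libraries and red bands mark 3 Mb on either side of the centromere. Medians fall towards the centromere on each chromosome, as in the difference of -2.12 between pericentromeres and arms.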

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

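The spread by the variance-to-mean ratio was chosen after seeing the data, and the other alternatives before. No paired analysis was possible because there is 1 group. Counts of detected genes stayed within 1.5 times the main count under each alternative. Of 26 list levels, all kept their call with a pseudocount of 0.1, with both scalings and without replicate 4 or 6. The cause was not tested for the changes given here, except that a filter takes low members out of a list, and an SD from 2 libraries rests on 1 difference.

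The mean Pearson r over pairs of libraries was 0.994618 with a pseudocount of 0.1 and 0.997727 after rescaling to a fixed sum, and 0.997938 to 0.997986 with each library left out. Genes over 2-fold in FPKM + 1 numbered 14 at 1 FPKM or more and 32 without a filter. Leaving out each library put the floral identity level between -2.40 and -2.37, and its call ended without replicate 5. Against genes at 1 FPKM or more, calls appeared for cytosine methylation (-0.96), heat shock (-2.18), cold (1.71), low oxygen (-2.16) and cell cycle (-1.26), and ended for seed storage (-2.11) and H3.1 (1.4). Floral identity and pollen genes gave no value there, with fewer than 3 members. With the mean over members, calls appeared for salicylate (-1.20), cold (1.46) and low oxygen (-1.47) and ended for H3.1 (2.02).

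Calls of spread were less stable. The Calvin cycle call ended after rescaling (0.0141) and with size factors (0.0154). Leaving out each library gave 0.0113 to 0.0154 for Calvin cycle, 0.0125 to 0.0211 for light harvesting, 0.0792 to 0.360 for seed storage, 0.0115 to 0.0330 for root markers, 0.0158 to 0.0599 for phosphate and 0.0521 to 0.138 for stomatal genes. With members at 10 FPKM or more, light harvesting (0.0168) and Calvin cycle (0.0134) were no longer called, and root markers (0.00607), shoot meristem (0.0209) and H3.1 (0.0902) were. By the variance-to-mean ratio, Calvin cycle reversed (4.19), light harvesting was not called (2.27), and flowering time (0.362), jasmonate (0.396) and shoot meristem (0.140) were called below. This ratio does not shrink with depth, as an SD does. Lists with fewer than 3 members of clear length and 100 reads gave no value there.

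The pericentromere difference was -3.21 with a pseudocount of 0.1, -2.34 after rescaling, -2.46 within 2 Mb and -1.12 within 5 Mb. The organelle share was 0.128% without the 10 highest genes. Of 102 values for contrasts, 86 moved by less than 1 SD and 15 by more in the same direction. MTA against MTB reversed without replicate 5 (0.030), with -0.101 to 0.030 over the libraries left out. At this depth a count of 0 in a library allows up to 0.151 FPKM in a gene of 1000 bp, and less in a longer gene.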

Other observations

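The tests of shared RNA, of multiply matching reads, of polyadenylated RNA and both tests of genes without shared words were chosen only after the result was seen. Those of mate pairs, of paralogs among all abundant genes and of harvest time were written before. The bootstrap intervals below resample genes within the same 3 libraries, so they measure no error between libraries.

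Photosynthetic antenna genes differed within the family. The 5 LHCB1 genes summed to 26592 ± 379 FPKM and the 3 LHCB2 genes to 123 ± 2.47 FPKM (n = 3), although both encode the trimeric antenna of photosystem II. LHCB2.1 and LHCB2.2 share 22.7% and 28.2% of their 50-base words with other genes, and LHCB2.3, which shares none, had 12.0 ± 0.431 FPKM. Of 13 root markers 4 were detected, PYK10 at 1196 ± 3.50 FPKM and SCR, SHR and CASP1 at 14.6, 10.4 and 4.27 FPKM. The other 9 were below 1 FPKM in every library. Among them were the root hair genes EXP7, COBL9 and RHD6 at 0.016, 0.070 and 0.156 FPKM. WOX5, PLT1 and PLT2 were also low, at 0.134, 0.392 and 0.133 FPKM. How much root tissue the samples held was not measured.

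Several evening-phased clock genes (TOC1, ELF4, LUX) were high and the morning-phased CCA1, LHY and PRR9 low, while RVE4, of the CCA1 family, was high at 95.4 FPKM. A hypothesis is harvest late in the light period or early in the dark. It was tested on 15 further genes, named for their known phase before their values were looked at. The median log2(FPKM + 1) of 7 evening genes exceeded that of 8 morning genes by 4.24 ± 0.025 (n = 3; 4.22 to 4.27), above the 2 set as the bound, in 3 of 3 libraries. BT2 and CAT3 among the evening genes had 533 ± 4.49 and 1852 ± 8.72 FPKM, and ELIP1 and COL2 among the morning genes 0.436 ± 0.087 and 10.6 ± 0.701 FPKM. RVE2, listed as a morning gene, went the other way at 238 ± 7.09 FPKM. The genes also differ in their average level over a day, which was not measured, so the result is consistent with an evening harvest without dating it.

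The first pattern weighed was the small difference between libraries. In 723 genes with 10000 reads or more, a variance of 1.35 times the mean was first removed, the ratio in genes of 100 to 300 reads. This took out more than Poisson counting, which is 1 times the mean. The median coefficient of variation left was 0.817% (95% bootstrap interval 0.724 to 1.01). Libraries from the same plants or RNA may differ this little, but the value restates the pattern and does not count for that explanation, and pools of seedlings grown together remain open too. Counting of both mates of a pair would make values of exactly 2 reads frequent. Their number over the mean of those of 1 and 3 reads was 0.893 (0.775 to 1.02), and an interval that holds 1 keeps this open. No biological explanation was tested, since there is 1 group.

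The second pattern was the larger spread of the most abundant genes. Reads shared between near-identical paralogs may add to it. Among genes with 10000 reads or more, the median variance-to-mean ratio of 12 genes with 20% or more shared words was 1.52 times (0.790 to 2.25) that of 625 genes with none, and 12 genes are too few to decide. In 28 genes with 100000 reads or more and no shared word the median was 2.49 (0.887 to 5.77), an interval that still holds the 0.920 of genes of 100 to 300 reads. Medians in this paragraph are unscaled, and the 0.920 corresponds to a scaled median of 1.33. A value below 1 thus does not mean less spread than Poisson counting. After the result in 28 genes the test was widened to all 625 genes without shared words, whose median of 1.28 (1.15 to 1.42) lay above 0.920. In these libraries, sharing of such words is thus not the whole cause in genes of 10000 reads or more. The 0.920 was taken as a fixed value, without an interval of its own. Most of the 625, 493 genes, had 10000 to 30000 reads and a median of 1.18. The widened test therefore does not decide for the most abundant genes. No biological explanation was tested.

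The third pattern was the low level of organelle genes in libraries whose protocol removes ribosomal RNA. Leaving out reads with more than 1 match could lower genes with repeated sequence, but not genes without it. Of the chloroplast genome's 50-base words 35.4% occur elsewhere, mostly in its own repeat (34.0%), and 56 of its 85 annotated protein-coding genes hold no such word. These would keep their reads, yet no chloroplast gene in the files had a mean above 78.0 FPKM. Chloroplast identifiers in the files and the annotation could not be matched. The lowest 32 of 88 rows were therefore taken out in place of the genes with repeated words and of rows beyond the annotated genes. The median of the 56 rows left, 4.05 FPKM (95% bootstrap interval 3.14 to 5.58), is the highest that genes without repeated words can have. The interval holds the 4.71 FPKM of the median nuclear gene, the bound set for this test after the low levels were seen, so the test did not decide. All 88 chloroplast rows, with the genes without repeated words among them, had at most 78.0 FPKM. Such genes keep their reads under this explanation, so it could not have lowered them. Whether their levels count as low depends on the bound chosen, and the test did not settle that. Chloroplast genes with repeated words are outside that test. An earlier bound of 100 FPKM, also set after the levels were seen, would have been decided against this explanation. Of the mitochondrial genome's words 71.1% occur elsewhere, so it stays open for mitochondrial genes. Selection of polyadenylated RNA, or removal of organelle reads before deposit, remains open as well, since organelle genes held 0.116% of summed FPKM (0.112 to 0.120), and no class of unpolyadenylated nuclear RNA was analysed here. No biological explanation was tested.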
